A study of Homo sapiens with 8 samples.

How the data were processed

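The data were ATAC-seq peak lists of 8 libraries from human coronary artery smooth muscle cells, 4 labelled shCtrl and 4 labelled shSUV39H1, grouped by their sample titles. Libraries were made with the ATAC-Seq Kit of Active Motif, per the labels. The submitters' processing notes name genome build hg38, Trim Galore 0.6.7, Bowtie2 2.5.1, SAMtools 1.21, Picard 2.25.6, bedtools 2.30.0, deepTools 3.5.5, MACS3 3.0.1, DESeq2 1.44.0, HOMER 5.1 and ChIPseeker, without their roles or order. Settings of the peak caller, filters on duplicate or multiply aligned reads, any shift of reads for the transposase and the number of reads were not given in the sources used here. These steps set which short or repeated sequences can appear as peaks.

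Each list was called on 1 library, so the library was the replicate, and pooled calls were not used. In the deposited lists each peak carries a score, which is 10 times its -log10 q as a whole number, and the authors' fold enrichment at the summit, a ratio over the local background of the same library. The -log10 p and the -log10 q per peak are also the authors' own values, and the smallest -log10 q was 2.00, so the lists hold q-values up to 0.00999. Fold, score and -log10 q were used to rank or filter peaks within a list, because values of lists of unlike depth are not comparable. The mean -log10 q over the 4 libraries that called a gained or lost region served only to choose which regions to name. Comparisons rest on where peaks were called. This leaves the 104674 regions called in all 8 libraries without a test of their height.

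Read depth was not given. The number of fragments at the summit and the local background were recovered from fold and p, assuming that fold is (pileup + 1)/(background + 1) and that p is a Poisson tail; 99.8% of pileups then came out whole within 0.01. The lowest background of a list was taken as its genome-wide coverage per bp and ran from 0.567 to 1.02, and the lists held 150544 to 172081 peaks. A shallower library misses weak peaks, so absence of a call is weaker evidence than its presence. The share of identical intervals in any pair of lists was at most 0.267%, so no list repeats another.

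Chromosomes 1 to 22 and X were analysed, and chromosome Y was left out. Genes came from a RefSeq table of protein-coding genes of GRCh38.p14, which is the same build as hg38, with 19974 genes after this filter. The table gives gene ends and no strand, exons or sequence. The planned split into promoters, exons and introns was therefore replaced by distance to either end of a gene, and the planned count of 20 sequence motifs, the share of soft-masked sequence and the domain of 2 kb around gene starts were not run. For the same reason exon or intron positions of regions are not given.

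Intervals of the 8 lists that overlapped by at least 1 bp were merged into regions, and a region was present in a library with a peak in it. A region was gained when called in 4 of 4 shSUV39H1 and 0 of 4 shCtrl libraries, and lost in the reverse case. Values per library were compared by an exact two-sided permutation test over all 70 assignments, whose smallest p is 0.0286. Similarity of libraries was the Jaccard index of covered bases, with the labels permuted. Region classes were compared by Fisher's exact test.

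Peak numbers per gene (gene body with 10 kb on each side, mean of at least 2 peaks) and per 1 Mb window (mean of at least 5 peaks) were scaled to the mean library total and tested as log2(number + 0.5) with limma 3.58.1 (trend and robust), adjusted by the method of Benjamini and Hochberg, with a threshold of 0.05. Log2 changes are on this scale, which understates the change where numbers are low. These numbers are computed from peak calls and are not read numbers, so no model of read counts was used. Gene lists were tested with camera at a preset correlation of 0.01, with an estimated correlation, with fry and with permutation of list means. The 18 lists covered contractile genes, their regulators, Krüppel-like and pluripotency factors, matrix, osteochondrogenic, inflammatory and proliferation genes, and H3K9 and DNA methylation. They also covered markers of endothelium, fibroblasts, leukocytes, epithelium and cardiomyocytes, housekeeping genes, KRAB zinc finger genes, olfactory receptors, the protocadherin cluster and HOX genes. The zinc finger list is defined by gene symbol and chromosome, so it can hold members without a KRAB domain. For windows, ZNF genes are those whose symbol is ZNF followed by a number alone, so ZNF280D and other zinc finger genes were not counted. Neighbouring genes of a cluster share peaks within 10 kb, so their values are not independent.

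The groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule named KLF4 and SUV39H1 and members of a list that passed over all genes or over the list alone (at most 4 per list). It also named the 10 genes up and down with the largest change among those that passed (or else the 5 of smallest p in each direction), the 10 gained and 10 lost regions of highest mean -log10 q, and the 5 windows up and down of smallest p. Alternatives were a -log10 q of at least 5, peaks of at least 300 bp, the same number of peaks per library (146781, those of highest -log10 q), coverage of at least 50% of a region, windows of 500 bp on summits and a rule of 3 of 4 libraries. Others were other pseudocounts, filters, scalings, gene flanks of 50 kb, windows of 250 kb, gene ends of 3 kb, the replicate number as a block, and leaving out each library. Lists thinned to a common depth were added after the data were seen: pileup and background were scaled to the lowest background coverage, and peaks were kept that passed the p passed by 99% of the peaks of that library.

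The scripts were tested on simulated peaks. Of 100 planted gained and 100 planted lost regions, 100 and 100 were recovered among 220757 regions. These regions were planted by the same rule that calls them, so their recovery was fixed in advance and checks only the counting. Of 50 genes per fold, among 15849 tested, 58% were recovered at a fold of 2, 20% at 1.5, 4% at 0.667 and 22% at 0.5. For windows, among 2621 tested, 98% were recovered at folds of 2 and 1.5 and 100% at 0.667 and 0.5, with 1.49% of calls false. Changes were planted only where peak numbers lay above the lowest admitted to the real tests. Simulated regions were drawn independently of their neighbours, so recovery in the real lists may be lower and the share of false calls higher. The windows called in the real lists had median log2 changes of -0.224 (fewer peaks) and 0.203 (more peaks), smaller than any planted change. Recovery at that size was not measured. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and R 4.3.3.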

Results

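Open chromatin was profiled by ATAC-seq, in which a transposase places sequencing adapters into accessible DNA, in human coronary artery smooth muscle cells (HCASMC), the contractile cells in the wall of the arteries that supply the heart. The series describes the comparison as cells with and without knockdown of SUV39H1, a histone methyltransferase that deposits the H3K9me3 mark of constitutive heterochromatin, and its title names KLF4, a transcription factor linked to the loss of the contractile state, and chromatin remodeling. There were 8 libraries in 2 groups, 4 labelled shCtrl and 4 labelled shSUV39H1, with replicates numbered 1 to 4 in each group. One list of ATAC-seq peaks in hg38 coordinates was analysed per library. SUV39H1 transcript or protein was not measured by this assay, so the extent of the knockdown was not checked here. The labels do not say that the replicates were separate cultures or donors, so the p-values measure only the spread between these libraries, which may be technical.

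No measure of how much open chromatin was called passed the threshold between the shSUV39H1 and shCtrl libraries. The lists held 157048 ± 6939 peaks (SD, n = 4) in shSUV39H1 and 162722 ± 3951 (SD, n = 4) in shCtrl on chromosomes 1 to 22 and X, an exact two-sided permutation p of 0.229. Peaks covered 44.1 ± 3.61 Mb against 49.7 ± 5.38 Mb (exact permutation p = 0.2), and the median peak width was 209 ± 9.6 bp against 226 ± 19.9 bp (exact permutation p = 0.229). The background coverage per bp recovered from the lists, which stands in for sequencing depth, was 0.645 ± 0.0733 against 0.771 ± 0.174 (exact permutation p = 0.257). Adjusted over these 4 measures, every p was 0.257. Covered length and median width were nevertheless lower in each shSUV39H1 library than in the shCtrl library of the same replicate number. Their sign flip p with the replicate block was 0.125, the smallest that 4 pairs allow, against 0.25 for the number of peaks. Background coverage was also lower in each of these pairs, so lower depth cannot be told apart from less open chromatin. The background coverage ran from 0.567 in shSUV39H1 replicate 4 to 1.02 in shCtrl replicate 3, and these libraries also had the fewest (146781) and the most (167643) peaks.

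**Figure D1:**
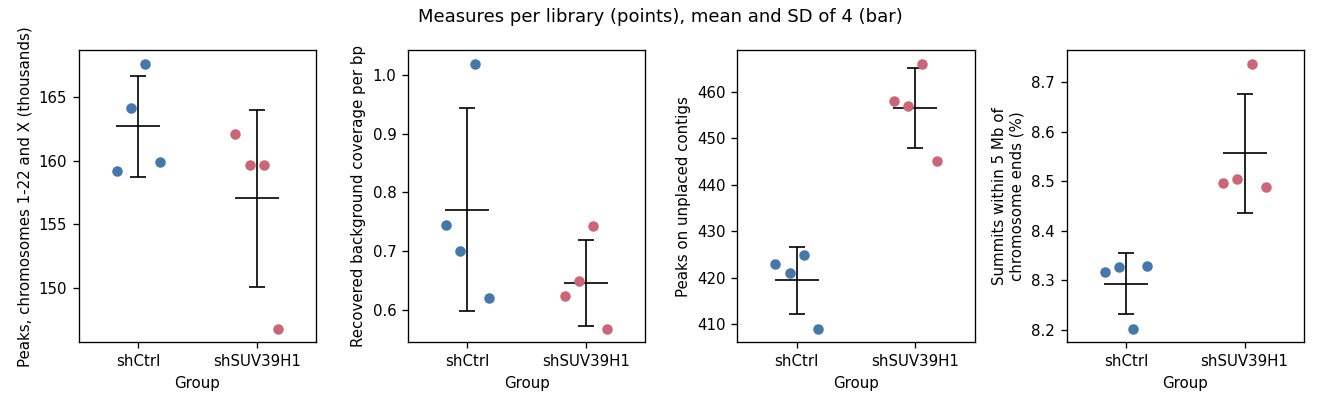
Each point is 1 library and the bars give the mean and SD of 4 libraries, for the number of peaks, the recovered background coverage per bp, the number of peaks on unplaced contigs and the percentage of summits within 5 Mb of a chromosome end, by group. Unplaced contigs here include those assigned to a chromosome but not to a position on it. The groups overlap in peak number and background coverage, while the 4 shSUV39H1 libraries lie above the 4 shCtrl libraries on unplaced contigs (445 to 466 against 409 to 425) and near chromosome ends.

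Peaks of the 8 lists merged into 220757 regions, of which 104674 were called in all 8 libraries. Knockdown libraries shared 632 regions that no control library had (gained), and control libraries shared 1483 regions that no knockdown library had (lost). With the same number of peaks per library these counts were 865 and 1171, a smaller imbalance. Among the gained regions with the highest mean -log10 q, the authors' own value per peak were sites inside SF3B1, a core splicing factor (chromosome 2, 197422760 to 197422896, mean -log10 q of 28.1), and NT5C2, a cytosolic nucleotidase (chromosome 10, 103139890 to 103140059, 27.2). Others lay inside XRN2, a nuclear exoribonuclease (chromosome 20, 21380492 to 21380612, 21.4), and ENAH, a regulator of actin filaments (chromosome 1, 225576148 to 225576260, 20.8). The other 6 of the leading 10 lay inside NME7, GRIK2, a glutamate receptor subunit, PCDH9, a protocadherin, PCMT1, ZNF398, a zinc finger gene, and 6.6 kb from RFK, with means from 20.4 to 22.7.

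Among the lost regions, the leading one lay outside genes, 95.5 kb from SPATA18 (chromosome 4, 52192826 to 52193161, mean -log10 q of 29.6). Others lay inside PRDM1, a transcriptional repressor (chromosome 6, 106025705 to 106026014, 22.7), inside SYNPO2, an actin-binding protein of smooth muscle on the contractile list (chromosome 4, 118954368 to 118954516, 22.1), and 52.7 kb from BMP4, a secreted growth factor (chromosome 14, 53896884 to 53897084, 19.9). The remaining ones were inside PRDM10 and LCLAT1, 52.1 kb from PCDH1, 30.8 kb from SHISAL2B, 6.95 kb from SERTM1 and 1716 kb from ARAP2. A lost region also lay inside CALD1, an actin- and myosin-binding protein on the contractile list (chromosome 7, 134758057 to 134758181), and 0 gained regions lay within 10 kb of genes on that list. Regulators of the contractile state had 5 lost regions, in ZEB2, MEF2A, MRTFA and at 2 sites in PRKG1, the cGMP-dependent kinase of vessel relaxation, and 1 gained region, also in PRKG1. By Fisher's exact test against the other regions called in 4 libraries, no list held more or fewer gained or lost regions than expected (smallest adjusted p = 0.753 over 36 tests).

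Gained and lost regions had median widths of 187 bp and 227 bp, against 190 bp for the 9507 other regions called in 4 libraries. Within 1 kb of either end of a protein-coding gene lay 29 gained regions (4.59%) and 38 lost regions (2.56%), which differed by Fisher's exact test over regions (two-sided p = 0.0204), and 5.81% of the other regions called in 4 libraries. Neighbouring regions are not independent, so this p is too small. No single region can pass adjustment in a design of 4 against 4, where the smallest exact p is 0.0286. A gained or lost region requires all 8 calls, so leaving out a library relaxes the rule: there were 1029 gained regions without shCtrl replicate 3, 963 without shSUV39H1 replicate 2 and 1363 without shSUV39H1 replicate 4, and 2255 and 2383 lost regions without shCtrl replicates 1 and 4.

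**Figure D2:**
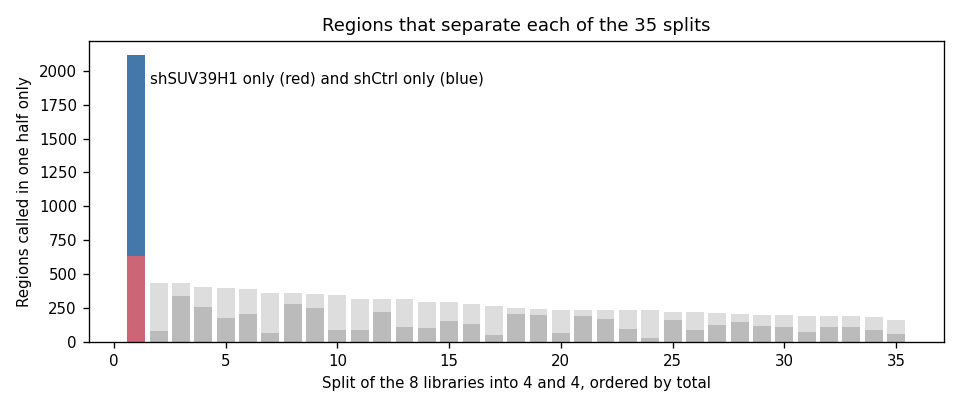
Each bar is 1 of the 35 ways to divide the 8 libraries into 4 and 4, ordered by the number of regions called in all 4 libraries of one side and none of the other, and the shades of a bar show the sides. The division into shSUV39H1 (red, 632 regions) and shCtrl (blue, 1483 regions) gives 2115 regions and the next highest gives 437.

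Libraries of one group also shared more of their accessible sequence. The mean Jaccard index of covered bases was 0.659 ± 0.0136 (SD, 12 pairs) within groups and 0.633 ± 0.016 (SD, 16 pairs) between groups, a difference of 0.0251 (exact two-sided permutation p = 0.0286, the smallest that 70 assignments allow).

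At KLF4 (chromosome 9, 107484852 to 107489769), the gene named in the study's title, peak calls were largely shared by the groups. Of 21 regions within 100 kb of the gene, 11 were called in all 8 libraries, 0 were gained and 0 were lost. The region at the upper end of the gene (107489716 to 107490801) was called in all 8 libraries, and the one inside the gene (107488404 to 107488806) in all but shSUV39H1 replicate 1. The largest imbalances were regions at 107397750 to 107398094, 86.8 kb below the gene, and at 107586585 to 107586740, 96.8 kb above it, each called in 4 shCtrl libraries and 1 shSUV39H1 library. The gene with 10 kb on each side held 3.75 ± 0.5 peaks in shSUV39H1 and 4 ± 0 in shCtrl (SD, n = 4), a log2 change of -0.04 (SE 0.13, limma adjusted p = 0.93). That direction turned to 0.06 without shSUV39H1 replicate 1 and to 0.05 with 50 kb on each side. Peak presence does not measure how open a shared region was, and a change in height at these regions was not tested here.

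**Figure D3:**
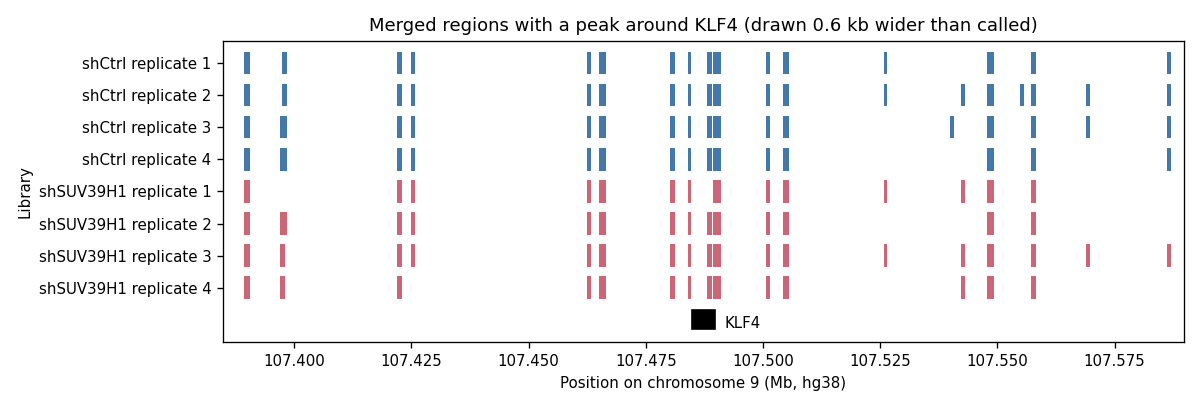
Blocks mark the merged regions in which each library (rows, shCtrl blue and shSUV39H1 red) had a peak within 100 kb of KLF4 (black) along chromosome 9 in Mb, each block drawn slightly wider than called so that it can be seen. The 11 regions called in all 8 libraries include the one over the upper end of the gene.

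At SUV39H1 itself (chromosome X, 48695554 to 48709016), 6 regions lay within 10 kb and 3 were called in all 8 libraries. There were 6.25 ± 0.5 peaks in shSUV39H1 and 5.75 ± 0.5 in shCtrl (SD, n = 4), a log2 change of 0.16 (SE 0.11, limma adjusted p = 0.639), which turned to -0.10 in the list restricted to a -log10 q of at least 5.

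Across 16168 protein-coding genes, each taken with 10 kb on either side, 0 had more and 0 had fewer peaks in shSUV39H1 at a limma adjusted p under 0.05, and 1735 had an unadjusted p under 0.05. With the same number of peaks taken from each library, 35 genes had more and 31 fewer, but 51 of these 66 had no spread in either group, as happens with small whole numbers. Among the genes of smallest p with more peaks, EARS2, the mitochondrial glutamyl-tRNA synthetase, had 7.25 ± 0.5 peaks in shSUV39H1 and 4.25 ± 0.5 in shCtrl (SD, n = 4), a log2 change of 0.76 (SE 0.12). The log2 change was 0.99 (SE 0.15) at DENND4C, 0.66 (SE 0.12) at SEC24C, a coat protein of vesicles leaving the endoplasmic reticulum, 0.68 (SE 0.13) at MFSD12 and 0.40 (SE 0.08) at TMEM272. Among those with fewer peaks, PHC3, a Polycomb protein, had 4.75 ± 0.5 against 8.75 ± 1.26 peaks, a log2 change of -0.76 (SE 0.13). LCLAT1, a lysocardiolipin acyltransferase, was at -0.49 (SE 0.08), LOC100996709 at -0.85 (SE 0.14), SLC9C1 at -0.78 (SE 0.13) and the defensin gene DEFB134 at -1.15 (SE 0.20). For these 10 genes the values of the groups did not overlap and the limma adjusted p was 0.153, so none passed. With depth-matched lists EARS2 alone passed (limma adjusted p = 0.0331). LOC100996709 was at -0.18 with the same number of peaks per library and at -0.26 with a -log10 q of at least 5, where EARS2 was at 0.46 and LCLAT1 at -0.31. SEC24C was at 0.43 with the same number of peaks per library. With 50 kb on each side the log2 changes were smaller, 0.38 at DENND4C, 0.32 at EARS2, 0.29 at SEC24C, 0.35 at MFSD12, -0.32 at PHC3, -0.24 at LCLAT1, -0.32 at SLC9C1 and -0.17 at DEFB134. A test on simulated peaks recovered 58% of genes with a planted doubling and 22% of those with a planted halving, so changes of this size could be missed. Genes with the lowest peak numbers were not among those planted.

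Of the 18 gene lists fixed before the data were examined, 0 passed as a group (camera, preset correlation of 0.01, adjusted over the lists) and 0 with an estimated correlation. Over all genes 0 list members passed, and 4 did when adjusted over the list alone. Those 4 were KLF12, a Krüppel-like repressor, with 43.3 ± 2.22 against 51 ± 3.46 peaks (log2 change -0.18, SE 0.04, adjusted p of 0.0262 over the list and 0.205 over all genes), and DCN, the matrix proteoglycan decorin, with 5.75 ± 1.26 against 9 ± 0.816 (log2 change -0.58, SE 0.14, 0.0421 and 0.202). The others were MKI67, the proliferation marker Ki-67, with 3.5 ± 0.577 against 2 ± 0 (log2 change 0.71, SE 0.15, 0.00999 and 0.157), and SOX17, an endothelial transcription factor, with 7.25 ± 1.5 against 4.75 ± 0.5 (log2 change 0.60, SE 0.15, 0.0341 and 0.215). Each of these had 4 libraries per group and groups that did not overlap. MKI67 was at 0.33 with the same number of peaks per library, 0.26 with a -log10 q of at least 5 and 0.23 with 50 kb on each side, where DCN was at -0.21 and SOX17 at 0.26.

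Over all 16168 tested genes the median log2 change was 0.0390, so 0 is not the centre for the counts in this and the next paragraph. Contractile genes went both ways, 12 of 24 tested members above 0 and 12 below (limma camera, adjusted p = 0.753). MYLK, the myosin light chain kinase, had a log2 change of 0.15 (SE 0.04) and ITGA8, an integrin of smooth muscle, -0.27 (SE 0.08). ACTA2, the smooth muscle actin, held 10.75 ± 0.5 peaks against 11.25 ± 2.06, and MYH11, the smooth muscle myosin heavy chain, 9 ± 1.41 against 10.5 ± 3. Of 23 regulators of the contractile state, 5 were above 0 and 18 below (limma camera, adjusted p = 0.664), with PRKG1 at -0.09 (SE 0.04), the transcription factors ZEB2 at -0.23 (SE 0.11) and MEF2A at -0.22 (SE 0.11), MYOCD, the coactivator that drives contractile genes, at 0.18 (SE 0.08) and JAG1, a Notch ligand, at 0.30 (SE 0.12). Krüppel-like and pluripotency factors were split 9 to 9 and matrix genes 16 to 17 (limma camera, adjusted p = 0.907 for each), with COL1A1, a chain of type I collagen, at 0.49 (SE 0.16). Osteochondrogenic genes were split 12 to 10 (limma camera, adjusted p = 0.958), with SP7 at 0.45 (SE 0.12) and COL2A1 at -0.39 (SE 0.11). Inflammatory genes were split 12 to 13 (limma camera, adjusted p = 0.736). Proliferation genes were split 11 to 13 and regulators of H3K9 and DNA methylation 20 to 7 (limma camera, adjusted p = 0.958 for each). None of these single genes passed over all genes. Apart from the 4 list members given above, the genes in this and the next paragraph were chosen after their values were seen.

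Markers of other cell types did not separate the groups as lists. The members above and below 0 numbered 7 and 8 for endothelial markers (limma camera, adjusted p = 0.753) and 7 and 8 for fibroblast markers (0.659), the latter with PDGFRA, a growth factor receptor, at -0.36 (SE 0.11). They numbered 8 and 5 for leukocyte markers (limma camera, adjusted p = 0.907), 7 and 5 for epithelial markers (0.958) and 5 and 4 for cardiomyocyte markers (0.958). Housekeeping genes were 11 above and 5 below (limma camera, adjusted p = 0.736), olfactory receptor genes 28 and 11 (0.958) and HOX genes 10 and 16 (0.736). The smallest values belonged to the gene clusters. KRAB zinc finger genes of chromosome 19 had 125 of 169 members above 0 (limma camera adjusted p = 0.177, and 0.955 with an estimated correlation). Their median log2 change was 0.0447, close to the 0.0390 over all tested genes, and their mean was 0.0895. ZNF793 was at 0.96 (SE 0.22) and ZNF699 at 0.60 (SE 0.15). The protocadherin cluster of chromosome 5 had 21 members above 0 and 16 below (limma camera, direction down, adjusted p = 0.177, and 0.955 with an estimated correlation), with PCDHAC2 at -0.56 (SE 0.15). The zinc finger list passed with a -log10 q of at least 5 (limma camera, adjusted p = 0.0451), and the protocadherin list passed without shSUV39H1 replicate 3 (0.0372) or without shSUV39H1 replicate 4 (0.0212). In 6 of the 18 lists the median, the mean and the camera test did not share a sign, among them the protocadherin, proliferation and Krüppel-like lists.

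Over windows of 1 Mb, broad parts of several chromosomes differed in peak number. Of 2625 windows, 25 had more and 28 had fewer peaks in shSUV39H1 (limma, adjusted p under 0.05). More peaks lay on chromosome 7 at 56 to 57 Mb, which holds CCT6A and CHCHD2 (34.8 ± 2.06 against 26.5 ± 2.38 peaks, log2 change 0.44, SE 0.08, adjusted p = 0.000714). They also lay on chromosome 19 at 19 to 20 Mb, with 29 genes of which 6 are zinc finger genes named ZNF (92.3 ± 5.12 against 83 ± 1.83, 0.20, SE 0.04, 0.00355). The window of JAG1 on chromosome 20 at 10 to 11 Mb also had more (107.3 ± 4.5 against 99.3 ± 2.22, 0.16, SE 0.04, 0.0119). On chromosome 16, windows with more peaks lay at 24 to 25 Mb, around PRKCB, a protein kinase C gene (0.22, SE 0.05, 0.0119) and at 32 to 33 Mb (0.48, SE 0.12, 0.0183). Fewer peaks lay on chromosome 11 at 26 to 27 Mb around ANO3 (45 ± 4.55 against 58.5 ± 3.7, -0.33, SE 0.06, 0.000714) and on chromosome 12 at 28 to 29 Mb around CCDC91 (-0.26, SE 0.05, 0.00143). They also lay on chromosome 2 at 187 to 188 Mb, which holds CALCRL, a receptor of the vasodilator peptides adrenomedullin and CGRP, and TFPI, an inhibitor of coagulation (40 ± 0.816 against 52.3 ± 3.3, -0.33, SE 0.06, 0.00143). The window of P2RY12 and IGSF10 on chromosome 3 at 151 to 152 Mb (-0.23, SE 0.05, 0.00355) and that of BMP3 and PRKG2 on chromosome 4 at 81 to 82 Mb (-0.29, SE 0.07, 0.0119) had fewer too. In each of these 10 windows the values of the groups, scaled to the library totals, did not overlap. With the same number of peaks per library the windows of JAG1 (log2 change 0.10, limma adjusted p = 0.127), P2RY12 (-0.14, 0.0647) and PRKG2 (-0.23, 0.0512) no longer passed, and PRKG2 also did not with depth-matched lists (-0.20, 0.0749). With a -log10 q of at least 5 the same windows were at 0.11, -0.12 and -0.22 and did not pass (limma adjusted p = 0.0752, 0.128 and 0.066). Without scaling, those on chromosome 19 (limma adjusted p = 0.102), of JAG1 (0.192), of PRKCB (0.126) and on chromosome 16 at 32 to 33 Mb (0.0583) did not pass. Without the variance trend and robust fit, those of CALCRL and TFPI (limma adjusted p = 0.0555), on chromosome 19 (0.0625), of JAG1 (0.0957) and of P2RY12 (0.127) did not pass, at the same log2 changes. The window on chromosome 16 at 32 to 33 Mb also did not pass without shCtrl replicate 2 (limma adjusted p = 0.0519) or shSUV39H1 replicate 2 (0.059).

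Windows with more peaks were richer in genes, with a median of 11 protein-coding genes against 3 in windows with fewer peaks and 5 over all tested windows. Zinc finger genes whose symbol is ZNF and a number alone lay in 5 of the 25 windows with more peaks, in 0 of the 28 with fewer and in 189 of all 2625. ZNF280D, whose symbol ends in a letter and is not counted there, lay in a window with fewer peaks on chromosome 15 at 56 to 57 Mb. Without scaling to the library total, the counts were 1 more and 20 fewer, and without the variance trend and robust fit they were 6 and 3. They were 43 and 50 with depth-matched lists, and only 2 and 3 with windows of 250 kb. The number with more peaks was 15, 10, 13 and 12 without shCtrl replicates 1 to 4 in turn and 12, 6 and 11 without shSUV39H1 replicates 1 to 3. The number with fewer was 15, 11 and 18 without shCtrl replicates 1, 3 and 4 and 12 and 16 without shSUV39H1 replicates 2 and 3.

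**Figure D4:**
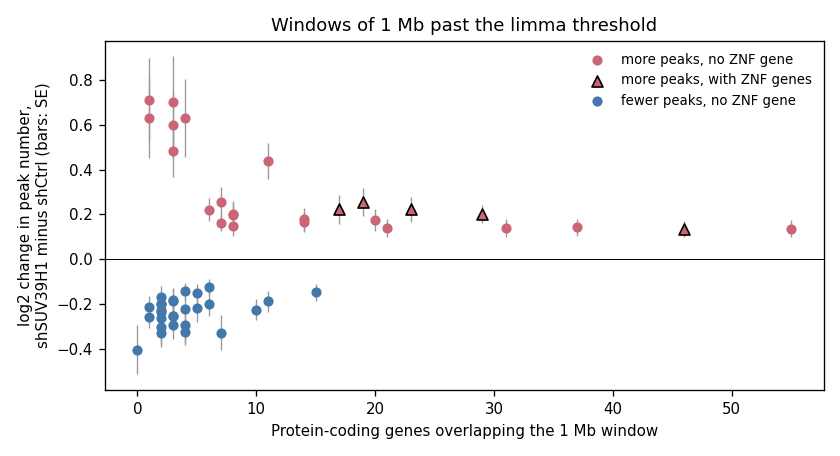
Each symbol is 1 of the 53 windows of 1 Mb past the threshold, with the number of protein-coding genes that overlap it on the horizontal axis and its log2 change in peak number (shSUV39H1 minus shCtrl, bars SE) on the vertical axis. Triangles mark the 5 windows with a gene whose symbol is ZNF and a number alone, all with more peaks, and other zinc finger genes are not marked.

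No difference in the position of peak summits relative to genes passed adjustment. Within 1 kb of either end of a protein-coding gene lay 11.1 ± 0.296% of summits in shSUV39H1 and 10.7 ± 0.382% in shCtrl (SD, n = 4, exact permutation p = 0.143). Elsewhere inside genes lay 46.7 ± 0.131% against 46.9 ± 0.22% (exact permutation p = 0.2), and outside genes 42.2 ± 0.17% against 42.4 ± 0.251% (exact permutation p = 0.2). Without shCtrl replicate 4 the difference near gene ends, 0.577 percentage points, and that outside genes, -0.319 points, each reached an exact permutation p of 0.0286. So did the difference elsewhere inside genes, -0.299 points, with gene ends taken as 3 kb (exact permutation p = 0.0286). The share within 5 Mb of chromosome ends was 8.56 ± 0.121% in shSUV39H1 and 8.29 ± 0.0614% in shCtrl, higher in every shSUV39H1 library than in any shCtrl library (exact permutation p = 0.0286). Adjusted over the 4 measures of this family it was 0.114 and did not pass. A single measure at the smallest possible p cannot pass this adjustment.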

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

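Of the tests in this part, those over all divisions of the libraries, the test of sequence copies, the test of depth on lost against gained regions and the ratios of log2 changes were chosen after the results were seen, and the form of the gene density correction was revised after its first result was seen.

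Single libraries stood apart from the other 3 of their group in several values, as chance does in about 1 in 20 groups. shSUV39H1 replicate 4 had 146781 peaks and 11.6% of summits within 1 kb of gene ends, and shSUV39H1 replicate 3 had a median peak width of 223 bp. Near chromosome ends the share was 8.20% in shCtrl replicate 3 and 8.74% in shSUV39H1 replicate 3. Among peak numbers of genes, where a step of 1 peak is enough to stand apart, the values were 3 at KLF4, 7 at SUV39H1, 4 at DENND4C, 8 at EARS2, 6 at SEC24C, 2 at LOC100996709, 4 at PHC3 and 7 at LCLAT1 in 1 shSUV39H1 library each. They were 5 at SUV39H1, 4 at SOX17, 3 at DENND4C, 5 at EARS2 and 5 at SEC24C in 1 shCtrl library each. Among the windows they were 14 peaks on chromosome 16 at 32 to 33 Mb, 64 on chromosome 11 at 26 to 27 Mb and 67 on chromosome 12 at 28 to 29 Mb, in 1 shCtrl library each.

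Unplaced contigs, here together with contigs assigned to a chromosome but not to a position, were left out of the comparisons above and are rich in repeated sequence. Peaks on them numbered 456.5 ± 8.66 in shSUV39H1 and 419.5 ± 7.19 in shCtrl (SD, n = 4), higher in each of the 4 shSUV39H1 libraries (exact permutation p = 0.0286, the smallest possible, not adjusted for the number of measures examined). List length argues the other way, since with the same number of peaks per library the difference was 54.3 (exact permutation p = 0.0286), and no single contig carried it: without the contig of largest difference it was 32 (exact permutation p = 0.0286), and 46 of 67 contigs were higher and 19 lower. Unequal handling of reads shared by sequence copies would raise alternate copies of placed sequence as well, if it affected both kinds of sequence alike. Their share had a log2 change of -0.00756 (SE 0.0354) against 0.17 (SE 0.0268) on unplaced contigs. Filters on multiply aligned reads were not given, and whether they affect both kinds alike was not tested, so such handling stays open. A more open state of repeat-rich heterochromatin under SUV39H1 knockdown is consistent with these values as a hypothesis, found and tested on the same libraries. A difference in the copy number of repeats was not tested and stays open.

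Lost regions outnumbered gained ones by 2.35 to 1, and the total of 2115 was not matched by any other division of the libraries (1 of 35, highest other 437). The highest place among 35 divisions is the most this design can give. The comparison was also chosen after the results were seen, so chance is not excluded for the total. The imbalance is ordinary, since the larger side exceeded the smaller by more than 2.35 times in 15 of the 34 other divisions, up to 5.91. Without shSUV39H1 replicate 4, the shallowest library, the ratio was 1.42, and since other divisions go far above 1, the bound of 1 set beforehand for this test was wrong and a single shallow library stays open. Lower depth of the shSUV39H1 libraries cannot be told apart from loss of open chromatin: the ratio was 1.35 with the same number of peaks per library, where other divisions reached 2.28, and 1.71 with depth-matched lists. The direction of the imbalance may thus come from depth, while the gained and lost regions together follow the groups.

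The 53 windows with changed peak number were not matched by another division of the libraries either (1 of 35, highest other 2). This too is the most the design can give, so chance is not excluded. With lists of the same length 26 of the 53 stayed past the threshold, 26 did not and 1 could not be tested. The bound set beforehand, that no fewer windows stay than not, was missed over all 53 and met over the 52 tested. The bound thus decides nothing, and list length may contribute. The log2 changes were a median 0.913 times those before (95% bootstrap interval 0.858 to 0.956, 52 windows), so most of their size remained. Both fits scale to the library total and the windows were chosen for large changes, so this ratio cannot settle the part of list length. The interval is over windows and leaves out the spread between libraries. The 26 calls that ended went from a median size of 0.19 to 0.14 at a median SE of 0.0528 and 0.0516. A straight-line trend of each library with log2 gene number was also removed. The log2 changes were then a median 0.985 times those before (0.977 to 0.997) and 39 of 53 windows stayed, so this trend did not carry most of their size. The form of this correction written first left 19, under the bound set beforehand, at 0.983 and 0.979 times the change for calls that stayed and ended. That form also altered the window means, and the prior degrees of freedom of the limma fit went from 58.4 to 8.83, against 61.3 in the revised form. The revision followed that result and only a straight line was removed, so other effects of gene density stay open. A change in copy number of long segments stays open, because neighbouring windows were correlated at 0.148, between the bounds set for and against it. Knockdown of SUV39H1 is among the open explanations, and no test here separates it from these.

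For single genes (limma, 0 past the threshold, 1735 at an unadjusted p under 0.05) and gene lists (camera, 0, of which 2 had an unadjusted p under 0.05), a comparison with other divisions of the libraries decides nothing, because every one of the 35 divisions gives at least 0 (35 of 35 for each). The highest other division gave 1 gene and 3 lists. With the same number of peaks per library, 66 genes passed against at most 26 in another division (1 of 35), but 51 of the 66 had no spread in either group.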

How the results depend on the processing

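The depth-matched lists were chosen after seeing the data; the other settings were planned. Numbers of peaks, covered length, median width and the similarity of libraries kept their direction and their side of the threshold in all settings run. Regions gained and lost numbered 3482 and 6720 under the rule of 3 of 4 libraries, which by construction is looser, and 889 to 1363 and 1909 to 2383 with single libraries left out (1029 without shCtrl replicate 3, 963 and 1363 without shSUV39H1 replicates 2 and 4, 2255 and 2383 without shCtrl replicates 1 and 4). Genes with more and fewer peaks, 0 and 0, numbered 35 and 31 with the same number of peaks per library, where 51 of 66 had no spread within groups and another division of the libraries gave 26. They numbered 1 and 0 with depth-matched lists, 0 and 1 with a -log10 q of at least 5, and 4 and 0 with gene flanks of 50 kb. Windows with more and fewer peaks, 25 and 28, numbered 43 and 50 with depth-matched lists, 1 and 20 without scaling (median shift -0.05), 6 and 3 without trend and robust fit, 2 and 3 at 250 kb, and 6 to 26 and 11 to 30 with single libraries left out, the lowest without shSUV39H1 replicate 2 (6 and 12) and shCtrl replicate 3 (13 and 11). No window of the 53 turned direction in any setting that kept windows of 1 Mb. Gene lists past the threshold, 0, numbered 1 with a -log10 q of at least 5 (zinc finger genes) and 0 to 1 with single libraries left out (1, the protocadherin cluster, without shSUV39H1 replicate 3 or 4). With an estimated correlation 0 lists passed, at a limma camera adjusted p of 0.955 for each of these 2. The share near gene ends differed by 0.269 to 0.577 points and that outside genes by -0.319 to -0.13 points with single libraries left out, and both passed without shCtrl replicate 4. The share elsewhere inside genes differed by -0.299 points with gene ends of 3 kb (exact permutation p = 0.0286). KLF4 turned to 0.0601 without shSUV39H1 replicate 1 and to 0.0492 with flanks of 50 kb, and SUV39H1 to -0.10 with a -log10 q of at least 5. Apart from the looser rule, the causes of these shifts were not tested.

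Groups share replicate numbers, and the labels do not say whether these mark a shared batch. In the presence of regions, same-numbered libraries deviated from their group means with correlations of -0.00241, -0.00281, 0.00545 and 0.0107. Only number 4 correlated best with its own. In both groups, however, covered length and background coverage were highest in replicate 3 and lowest in replicate 4. A batch shared by replicate number therefore stays open. With the replicate block, 28 windows had more and 33 fewer peaks, genes and lists stayed at 0, and the share near chromosome ends differed by 0.263 points at a sign flip p of 0.125, the smallest that 4 pairs allow. Sequence motifs at summits in all their settings and the domain of 2 kb around gene starts were not run, since no sequence or strand was at hand. Depth limits the absence of a call: background coverage of 0.567 in shSUV39H1 replicate 4 against 1.02 in shCtrl replicate 3 leaves weak peaks of the shallower library unseen.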

Other observations

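The zinc finger test below and the choice of windows named in the next paragraph were made after the data were seen; the test of sequence around chromosome gaps was planned before its result was seen.

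The windows of 1 Mb in this paragraph were picked for their genes and were not tested as a group. On chromosome 10, the window at 88 to 89 Mb with ACTA2, the smooth muscle actin, and FAS, a death receptor, had 74 ± 3.37 against 87.5 ± 3.7 peaks (SD, n = 4, log2 change -0.19, SE 0.05, limma adjusted p = 0.0174). The window at 52 to 53 Mb with part of PRKG1 and DKK1, a Wnt inhibitor, had 41.3 ± 1.89 against 51.3 ± 5.06 (-0.25, SE 0.06, 0.0196). The window of RGS4 and RGS5, regulators of G protein signalling in mural cells, on chromosome 1 at 163 to 164 Mb was at -0.25 (SE 0.06, 0.0119). The window of GJA1, a connexin, on chromosome 6 at 121 to 122 Mb was at -0.20 (SE 0.05, 0.0196), and that of YAP1 and a cluster of matrix metalloproteinase genes on chromosome 11 from 102 Mb at -0.15 (SE 0.04, 0.0299). Windows with more peaks included those of MRTFB, a coactivator of serum response factor, on chromosome 16 at 13 to 14 Mb (10.5 ± 1.29 against 7 ± 0.816 peaks, 0.60, SE 0.15, 0.0196), and of RHOA and LAMB2 on chromosome 3 at 49 to 50 Mb (0.14, SE 0.04, 0.0374). Others were those of PDGFB, a mitogen of smooth muscle cells, and CBX7 on chromosome 22 at 39 to 40 Mb (0.14, SE 0.04, 0.0498), and of SUV39H2, the paralog of SUV39H1, on chromosome 10 at 14 to 15 Mb (0.15, SE 0.04, 0.0487). Without scaling to the library total, the windows of MRTFB (limma adjusted p = 0.0583), RHOA (0.326), PDGFB (0.366) and SUV39H2 (0.331) did not pass. With the same number of peaks per library those of PRKG1 (log2 change -0.12, limma adjusted p = 0.355), YAP1 (-0.10, 0.0972), RHOA (0.09, 0.143), PDGFB (0.09, 0.191) and SUV39H2 (0.09, 0.22) did not pass. Without the variance trend and robust fit, of the windows in this paragraph the one of MRTFB alone passed (limma adjusted p = 0.0362). A window holds many peaks outside the named genes, and none of the named genes passed on its own.

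By chromosome, lost and gained regions were unevenly spread. Chromosome 19 had 20 gained and 15 lost regions and chromosome 5 had 19 gained and 104 lost, against 632 and 1483 in all (Fisher's exact test over regions, adjusted p = 0.0128 and 0.0052 over 23 chromosomes), and the other 21 chromosomes had an adjusted p of at least 0.262. The ratio of lost to gained regions was 0.75 on chromosome 19 and 5.47 on chromosome 5. It was also low on chromosomes 22 (1.08), 16 (1.24) and 20 (1.42) and high on X (3.5) and 4 (3.41), so these 2 were the ends of a spread. The cause of this spread was not tested. Regions of one chromosome are not independent, so these p-values are too small. Of the 20 gained regions on chromosome 19, 4 lay in genes of the zinc finger list, inside ZNF699 (9296368 to 9296716), ZNF507 (32351557 to 32351694), ZNF565 (36182626 to 36183041) and ZNF573 (37763104 to 37763226), and 2 lost sites lay inside ZNF254.

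The clusters of zinc finger genes are a known site of H3K9me3, and a hypothesis is that they may gain peaks under SUV39H1 knockdown beyond what their gene number brings. In 37 windows with at least 3 ZNF genes, the log2 peak number relative to windows without ZNF genes whose gene number lay within 2 was -0.42 ± 0.01 in shSUV39H1 and -0.47 ± 0.02 in shCtrl (SD, n = 4), a difference of 0.05 (exact permutation p = 0.0286, the smallest possible). Another 3 such windows were left out, having fewer than 5 windows to compare with. The test was prompted by the called windows, 3 of which hold at least 3 ZNF genes, and without all called windows the difference over 34 windows was 0.04 (exact permutation p = 0.0286). The difference was 0.05 with the same number of peaks per library and 0.05 to 0.06 with each library left out in turn (exact permutation p = 0.0286 throughout). The size is small, and these p-values were not adjusted for the number of measures examined. In the gene test, the list of KRAB zinc finger genes went up in 20 of 20 settings with an exact permutation p of 0.0286 for its mean, unadjusted for the number of lists. That permutation measures the list mean, a log2 change of 0.0895, from 0 and not from the mean of all tested genes. The median log2 change was 0.0390 over all tested genes and 0.0447 in the list. By camera the list passed in 1 setting, a -log10 q of at least 5 (limma camera, adjusted p = 0.0451). With an estimated correlation between members, the list was far from passing (limma camera, adjusted p = 0.955).

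A related hypothesis, that sequence around centromeres may gain peaks, was tested on the share of summits within 5 Mb of the widest peak-free gap of each chromosome, which was 5.97 ± 0.0314% in shSUV39H1 and 5.91 ± 0.0214% in shCtrl (SD, n = 4). The difference of 0.0643 points was in the direction of the hypothesis (exact permutation p = 0.0286, the smallest possible) and was 0.0543 with the same number of peaks per library. With single libraries left out it ranged from 0.0539 to 0.0786, at an exact permutation p of 0.0571 without shCtrl replicate 1, 2, 3 or 4. The p-values of this test were not adjusted for the number of measures examined. The widest gap was found from the lists and is not an annotated centromere, and it can be another assembly gap.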
